A study of mouse gut metagenome with 10 samples.

How the data were processed

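From the DNA of 10 fecal samples, the variable regions V1 and V2 of the 16S rRNA gene were amplified with the primers 27Fmod and 338R, and a further PCR added Nextera XT indexes, per the labels' protocols. Amplicons of this gene identify bacteria by sequence, and the share of reads assigned to a taxon is its relative abundance. For each sample the authors deposited 6 tables, from phylum to species, whose values are relative frequencies, a fraction between 0 and 1 of that sample's total, per the file headers. The lineages in the files carry rank prefixes from kingdom to species. The read processing, the classifier and the taxonomy database are not given in the sources used here.

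The 60 tables were checked before use. The fractions of each table summed to 1 within rounding, and the taxa of each level summed to those of the level above within 5e-06 percentage points. Values were multiplied by 100 to give percent. No counts are in the deposited fraction tables, so the depth per sample is not given. Low values within a sample fell at even steps, such as 0.00365%, 0.00548%, 0.00731% and 0.00913% in control replicate 5. A depth could be estimated from such steps, but this was not done. No interval or detection limit that needs the depth was computed, and a value of 0 means only that the taxon was listed at 0. PCR efficiency, primer fit and the number of gene copies per cell affect relative abundances, and a rise of one taxon lowers the others because the values sum to a constant. Families with a name held 81.9% of the community on average, named genera 20.4% and named species 4.45%, so species are not named as results. A taxon with no name at its level is called unnamed and one that was not resolved at that level is called unresolved, both after the nearest named rank.

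Samples were grouped by the genotype in their source name, 5 control and 5 cKO, and by the sex in their title. The animals are numbered in the titles and are listed as separate samples, but nothing in the labels states cages, litters or dates. Replicate numbers here follow the order of listing and pair no samples. The title conflict of control replicate 2 and the shared title number of cKO replicates 1 and 2 were not resolved, and both were handled by leaving out or averaging samples as alternatives. If cKO replicates 1 and 2 are the same animal, they are not independent, and only the alternatives that average them or leave either out allow for this.

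The tests, the samples in each, the alternatives and the rule for named taxa were fixed before the data were examined. Families, genera and species-level taxa were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend) on log2(percent + 0.01), for taxa above 0 in at least 4 of the 10 samples, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change on this scale understates the change of taxa near or under 0.01%. Sex was tested in the same way with genotype as a covariate, and the interaction of genotype and sex with both. Phyla with a mean of at least 0.1%, sums over 17 fixed groups of bacteria, the Firmicutes to Bacteroidetes ratio, the Shannon index and the number of genera were compared by exact two-sided permutation tests of the difference in means. The 252 assignments of 10 samples to 2 groups of 5 allow a smallest p of 0.00794. The 95% intervals of these differences are the shifts that the exact test does not reject. Whole communities were compared by PERMANOVA on Bray-Curtis distances of families with the 252 assignments enumerated. These were computed in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

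Named taxa are, at family and at genus level, those past the threshold, the 10 with the highest mean and, where fewer than 5 passed, the 5 with the smallest p. Each tested phylum, each fixed group present, families past the threshold for sex and the 3 families with the smallest p for the interaction are named as well. The other families in the text, such as those beside Turicibacteraceae in the sex comparison, were chosen after their values were seen.

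The limma test was tested on simulated data with the means and spread of these taxa, 100 simulations per fold size. Those with a difference changed 6 of 29 families, 9 of 45 genera or 10 of 50 species-level taxa at once by the same fold. Values were drawn independently on the log2 scale, without zeros or a constant sum. A single changed taxon was not simulated. For families the test recovered 13.7% of 2-fold, 60.8% of 4-fold, 87.2% of 8-fold and 92.2% of 16-fold differences. For genera the shares were 6.56%, 59.6%, 81.6% and 91.0%, and for species-level taxa 5.40%, 51.9%, 77.9% and 87.3%. Without any difference, 9 of 100 simulations of families held a false call. The exact test gave a p of at most 0.05 in 4.8% of simulations without a difference, and PERMANOVA in 4%.

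The alternatives were pseudocounts of 0.001% and 0.1%, no detection filter, a minimum mean of 0.1%, centred log ratios, exact tests in place of limma, limma with a trend, sex as a covariate, males alone, cKO replicates 1 and 2 averaged, unassigned bacteria left out, assignments within sex (120), other indices, distances and levels, and each sample left out in turn. Ranges of a log2 fold change over the alternatives are those of the limma fits, since the exact tests are in percentage points. Class and order tables were used only to look for signals that the other levels lacked.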

Results

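The fecal bacterial community was profiled by 16S rRNA gene sequencing in 10 samples from untreated mice of 2 genotypes. Control mice carried floxed alleles of Cxcl12, which encodes a chemokine, and no Cre driver is named for them (Cxcl12f/f, n = 5 samples). The other mice carried the same alleles together with Foxl1-cre (n = 5 samples) and are called cKO here after their titles. Foxl1 is a transcription factor gene active in mesenchymal cells beneath the gut epithelium. Each genotype was represented by 3 samples from males and 2 from females. For each sample the deposited values were relative abundances from phylum to species, with no read counts. The depth of each sample was not estimated. At species level, 41 to 53 taxa were listed above 0 in a sample, and the smallest value above 0 was 0.00299% to 0.00643%.

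The source name of each sample gave its genotype. The title of control replicate 2 reads f+ where the other controls read ff, although its source name is that of the other controls. The titles of cKO replicates 1 and 2 share the number 2, as male2 and male2-2, so these samples may come from the same animal. Their families differed by a Bray-Curtis distance of 0.319, and 6 of the 45 pairs of samples were at least that far apart, this pair included. They were therefore not treated as one library, and were kept as separate samples.

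Bacteroidetes and Firmicutes made up nearly the whole community in both genotypes. Bacteroidetes, mostly the family S24-7 (also called Muribaculaceae, common in mouse gut), had a relative abundance of 62.9% ± 8.07 (SD, n = 5) in controls and 61.0% ± 14.1 (SD, n = 5) in cKO mice. Firmicutes, which include the lactobacilli and the clostridia, had 34.7% ± 7.54 in controls and 36.1% ± 13.3 in cKO mice. Single samples ranged from 44.7% to 80.4% for Bacteroidetes and from 17.0% to 51.0% for Firmicutes, a spread far wider than the difference between the genotype means. In an exact two-sided permutation test the cKO minus control difference was -1.86 percentage points for Bacteroidetes (95% interval -18.6 to 15.5, p = 0.802). It was 1.32 percentage points for Firmicutes (95% interval -15.3 to 16.8, exact p = 0.849). With samples left out in turn, the difference ran from -6.70 to 2.22 percentage points for Bacteroidetes and from -2.42 to 6.10 for Firmicutes. The mean log2 ratio of Firmicutes to Bacteroidetes was -0.88 ± 0.53 (SD, n = 5) in controls and -0.83 ± 0.95 (SD, n = 5) in cKO mice, a difference of 0.05 (95% interval -1.17 to 1.14, exact p = 0.929).

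**Figure D1:**
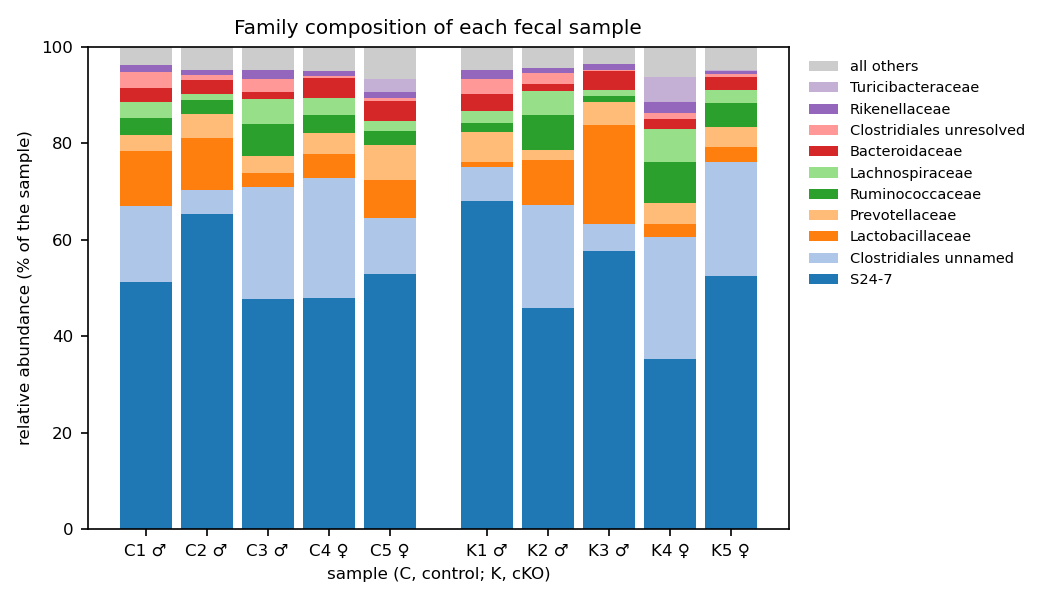
Stacked bars give the relative abundance, in percent of the sample, of the 10 families with the highest mean and of all others together, one bar per fecal sample, with controls on the left and cKO mice on the right. S24-7 was the largest family in each sample, from 35.3% in cKO replicate 4 to 68.2% in cKO replicate 1.

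The 5 less abundant phyla that were tested also overlapped between the genotypes. Proteobacteria had a relative abundance of 0.952% ± 0.220 (SD, n = 5) in controls and 1.03% ± 0.355 (SD, n = 5) in cKO mice (exact p = 0.659). Actinobacteria had 0.616% ± 0.265 and 0.767% ± 0.287 (exact p = 0.421), and TM7 had 0.353% ± 0.285 and 0.28% ± 0.192 (exact p = 0.667). Deferribacteres, represented by the mucus-dwelling genus Mucispirillum, had 0.402% ± 0.473 in controls and 0.455% ± 0.427 in cKO mice (exact p = 0.825). Tenericutes, bacteria without a cell wall, had 0.0283% ± 0.0118 (SD, n = 5) in controls and 0.35% ± 0.50 (SD, n = 5) in cKO mice. Their values in the cKO replicates 1 to 5 were 0.161%, 0.300%, 0.0438%, 1.22% and 0.0221%, and the highest control had 0.0416%. The difference of 0.321 percentage points (95% interval -0.00127 to 0.744) had an exact p of 0.0556, and 0.389 after Benjamini-Hochberg adjustment. Without cKO replicate 4 the difference was 0.103 percentage points, with the same exact p of 0.0556. Without cKO replicate 5, the lowest of the cKO samples, each remaining cKO sample lay above each control, with an exact p of 0.00794 and an adjusted p of 0.0556. The exact p was 0.0397 without cKO replicate 3 and 0.0333 with assignments within sex (adjusted 0.278 and 0.233), and 0.198 to 0.222 with any 1 control left out. With all 10 samples and all assignments, 0 of the 7 tested phyla passed an adjusted p of 0.05, and 0 had an unadjusted exact p under 0.05. The smallest exact p that the assignments allow, 0.00794, becomes 0.0556 after adjustment over 7 phyla. No phylum could therefore have passed alone, even with complete separation of the genotypes.

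At family level, the level that the study's design text names for comparing the genotypes, 29 of the 35 listed families were detected in at least 4 of the 10 samples and were tested. S24-7 had 53.1% ± 7.29 (SD, n = 5) in controls and 51.9% ± 12.3 (SD, n = 5) in cKO mice, a log2 fold change of -0.06 (95% interval -0.67 to 0.56). The clostridia without a family name were next, at 16.1% ± 8.32 and 16.6% ± 9.47, with a log2 fold change of -0.01 (95% interval -1.32 to 1.31). Lactobacillaceae, lactic acid fermenters, had 7.58% ± 3.73 in controls and 7.28% ± 8.02 in cKO mice, where single samples ranged from 0.986% to 20.5%. Their log2 fold change was -0.63 (95% interval -2.35 to 1.08), and ran from -1.20 to -0.10 over the alternatives.

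Among the families that degrade plant and host polysaccharides, Prevotellaceae had 4.62% ± 1.57 in controls and 4.33% ± 1.45 in cKO mice, and Bacteroidaceae had 3.16% ± 1.07 and 2.74% ± 0.969. Rikenellaceae had 1.29% ± 0.405 and 1.38% ± 0.618. The log2 fold changes of these 3 families were -0.11 (95% interval -0.93 to 0.70), -0.20 (-1.05 to 0.65) and 0.03 (-0.80 to 0.87), in that order. Ruminococcaceae and Lachnospiraceae, clostridial families with many butyrate producers, had 4.01% ± 1.59 and 3.02% ± 1.52 in controls against 4.82% ± 3.14 and 3.63% ± 2.22 in cKO mice. Their log2 fold changes were 0.01 (95% interval -1.19 to 1.22) and 0.22 (95% interval -0.98 to 1.42), and that of Ruminococcaceae was -0.64 among males alone. Clostridiales that were not resolved to a family had 1.64% ± 1.23 and 1.48% ± 1.20. Turicibacteraceae were listed at 0 in 3 of the 5 controls and in 3 of the 5 cKO samples, and reached 2.68% in control replicate 5 and 5.25% in cKO replicate 4.

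Anaeroplasmataceae, a family of Tenericutes, had the smallest p of the 29 families. They were listed above 0 in 2 of the 5 controls, at 0.0299% and 0.0198%, and in 4 of the 5 cKO samples, at 0.154%, 0.300%, 0.0256% and 1.16%. The log2 fold change of 2.83 (95% interval 0.31 to 5.34), on the scale of log2(percent + 0.01), had a limma adjusted p of 0.907, and the exact permutation test of the percentages gave an unadjusted p of 0.0873. Of the 5 cKO samples, 3 lay above the highest control. The log2 fold change was 1.99 without cKO replicate 4 and 3.71 without cKO replicate 5, and 4.22 and 1.34 with pseudocounts of 0.001% and 0.1%, and it did not pass in any of these (limma adjusted p from 0.0833 to 0.994 over the alternatives). The families with the next smallest p were Staphylococcaceae (0.0251% ± 0.0319 in controls, 0.00638% ± 0.00956 in cKO mice), Peptococcaceae (0.00613% ± 0.00858 and 0.0114% ± 0.00831) and Coriobacteriaceae (0.616% ± 0.265 and 0.767% ± 0.287), together with Lactobacillaceae. Each of these had a limma adjusted p of 0.993.

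With limma, 0 of the 29 families passed an adjusted p of 0.05, 1 (Anaeroplasmataceae) had an unadjusted p under 0.05, and the exact permutation test gave 0 families with an unadjusted p under 0.05. The unadjusted limma p of Anaeroplasmataceae ran from 0.00287 to 0.0711 over the alternatives. It was 0.0638 with cKO replicates 1 and 2 averaged. Of the 21 families with a mean of at least 0.1%, the 95% interval of the fold change lay within 4-fold in either direction for 14 and within 2-fold for 6. For rarer families the pseudocount limits the fold, so their narrow intervals do not bound it. In simulated families with the spread of these samples, 6 of 29 changed at once, the same test recovered 60.8% of 4-fold and 13.7% of 2-fold differences. Recovery of 1 changed family alone was not simulated.

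**Figure D2:**
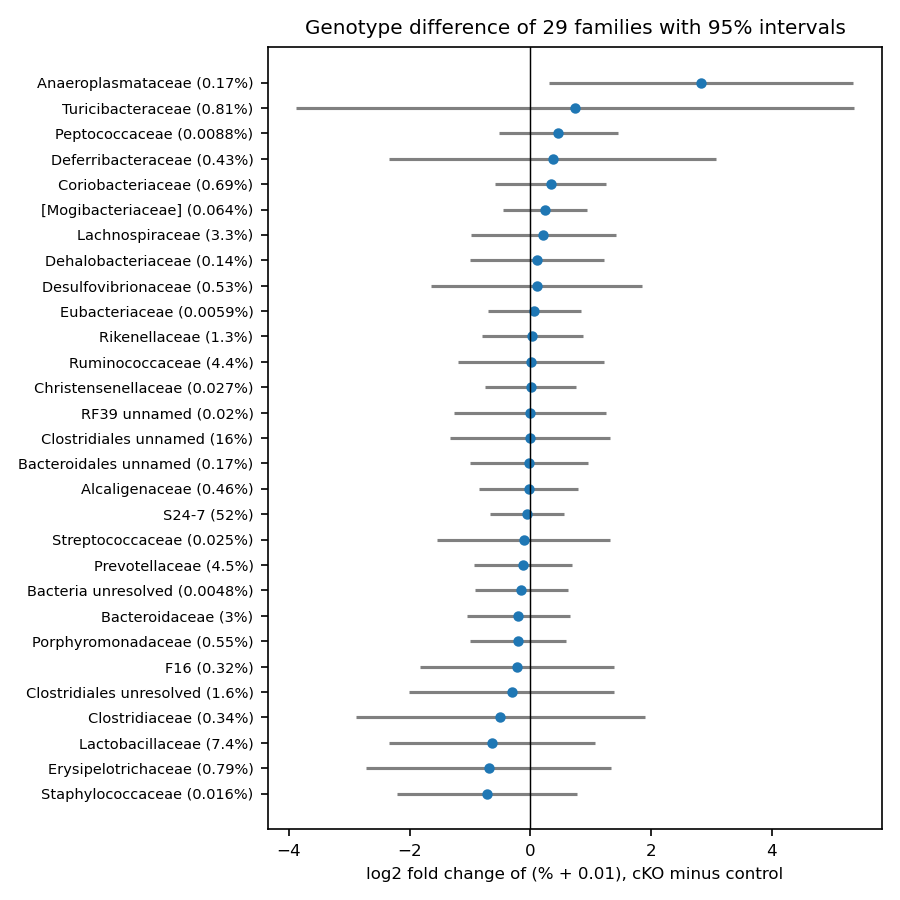
Points give the log2 fold change, cKO minus control, of relative abundance on the log2(percent + 0.01) scale for each of the 29 tested families, with the mean relative abundance over the 10 samples in brackets, and lines give the 95% interval of the limma fit. The interval of Anaeroplasmataceae, from 0.31 to 5.34, lies above 0 before adjustment for the number of families, and the interval of S24-7 runs from -0.67 to 0.56.

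At genus level 45 of 56 listed taxa were tested. Bacteroides, polysaccharide degraders, had 3.16% ± 1.07 (SD, n = 5) in controls and 2.74% ± 0.969 (SD, n = 5) in cKO mice, and Prevotella had 1.48% ± 0.347 and 1.25% ± 0.309. Prevotellaceae without a genus name had 3.15% ± 1.33 and 3.08% ± 1.27, and Lachnospiraceae without a genus name had 1.02% ± 0.478 and 1.30% ± 0.976. Oscillospira, a genus of Ruminococcaceae, had 2.25% ± 1.19 in controls and 2.79% ± 1.84 in cKO mice. The unnamed genera of S24-7, Rikenellaceae and Clostridiales, the unresolved Clostridiales and Lactobacillus each made up the whole of the listed family and had the family's values.

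The genus with the smallest p was Anaeroplasma, which held the whole of the Anaeroplasmataceae (log2 fold change 2.83, 95% interval 0.34 to 5.31, limma adjusted p = 0.994). Clostridium had 0.285% ± 0.298 in controls and 0.10% ± 0.123 in cKO mice, a log2 fold change of -1.43 (95% interval -3.50 to 0.65), which ran from -1.99 to -0.77 over the alternatives. Ruminococcaceae not resolved to a genus had 0.182% ± 0.226 and 0.429% ± 0.405, a log2 fold change of 1.19 (95% interval -0.74 to 3.13) that was 0.11 among males alone and at most 1.76 over the alternatives. Allobaculum was listed above 0 in 4 of the 5 controls and in 1 of the 5 cKO samples, at 0.0299%, 0.0217%, 0.0317% and 0.489% against 0.196%, a log2 fold change of -1.40 (95% interval -3.87 to 1.07). Among males alone it was above 0 in 3 of 3 controls and 0 of 3 cKO samples. The log2 fold change was -1.91 among males (limma adjusted p = 0.179) and -2.27 without cKO replicate 4 (limma adjusted p = 0.968), each with an unadjusted p under 0.05, and neither passed. It was -0.56 without control replicate 5, the sample at 0.489%, and -3.16 and -0.41 with pseudocounts of 0.001% and 0.1%. Dorea had 0.0316% ± 0.0223 and 0.0496% ± 0.0299. With limma, 0 of the 45 genera passed, 1 (Anaeroplasma) had an unadjusted p under 0.05, and 0 did in the exact permutation test. Of the 50 species-level taxa tested, 0 passed with limma, 1 (again Anaeroplasma, which had no species name) had an unadjusted p under 0.05, and 0 did in the exact permutation test.

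The fixed groups of bacteria did not separate the genotypes. The Bacteroidales families (S24-7, Bacteroidaceae, Prevotellaceae, Rikenellaceae and Porphyromonadaceae) summed to 62.7% ± 8.05 (SD, n = 5) in controls and 60.9% ± 13.99 (SD, n = 5) in cKO mice. The clostridial families with many butyrate producers (Lachnospiraceae, Ruminococcaceae, Clostridiaceae and Eubacteriaceae) summed to 7.38% ± 2.85 and 8.79% ± 5.37, and the lactic acid bacteria to 7.62% ± 3.76 and 7.31% ± 8.03. The 95% intervals of the cKO minus control difference were -18.6 to 15.4, -4.79 to 7.97 and -8.42 to 9.53 percentage points, in that order. Erysipelotrichia had 1.03% ± 0.952 and 0.541% ± 0.435, the sulfate-reducing Desulfovibrionaceae had 0.472% ± 0.313 and 0.597% ± 0.438, and Sutterella had 0.477% ± 0.222 and 0.437% ± 0.102. Coriobacteria, Deferribacteres and Saccharibacteria (TM7) held the same bacteria as the family or phyla given above.

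Segmented filamentous bacteria (Candidatus Arthromitus), which attach to the ileal epithelium, were listed at 0.246% and 0.00731% in control replicates 1 and 5 and at 0.418% and 0.0314% in cKO replicates 1 and 4, and at 0 in the other 6 samples. The mucin-degrading Verrucomicrobia (Akkermansia) were listed only in control replicates 2 and 4, at 0.00592% and 0.00390%. Environmental, skin and reagent families summed to 0.0272% ± 0.0302 in controls and 0.00727% ± 0.0102 in cKO mice. Bacteria with no phylum made up 0.00547% ± 0.00455 and 0.00421% ± 0.00552. Bifidobacteria, Enterobacteria, Epsilonproteobacteria and sequences of diet or host had no lineage listed in any of the 10 samples. In exact permutation tests, 0 of the 13 groups present passed, the lowest unadjusted p was 0.270, for the environmental, skin and reagent families, and the lowest adjusted p was 0.894. With a smallest possible exact p of 0.00794, 1 group alone could not have passed after adjustment over 13 groups.

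Diversity within samples did not separate the genotypes either. The Shannon index of genera was 1.78 ± 0.164 (SD, n = 5) in controls and 1.77 ± 0.321 (SD, n = 5) in cKO mice, a difference of -0.00897 (95% interval -0.363 to 0.425, exact p = 0.976). The number of genera above 0, which depends on a depth that was not estimated, was 41.6 ± 2.51 and 40.2 ± 3.96, a difference of -1.4 (95% interval -6 to 3.5, exact p = 0.571). Without cKO replicate 4 this difference was -3.1 (exact p = 0.0952), and over the other alternatives it ran from -2.05 to 0.2. For the whole community at family level, genotype accounted for 1.25% of the squared Bray-Curtis distances (exact permutation test, p = 0.944). Over the alternatives this share ran from 0.585% to 7.57%. The mean distance was 0.187 between controls, 0.267 between cKO samples and 0.202 between samples of different genotype.

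**Figure D3:**
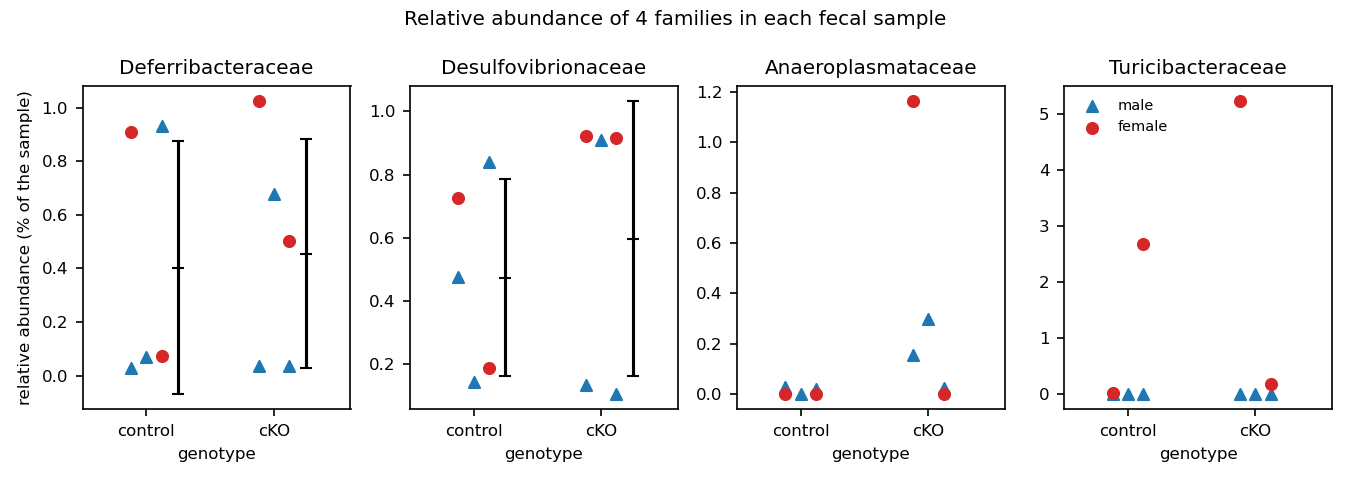
Each panel gives the relative abundance of one family, in percent of the sample, in the 10 fecal samples by genotype, with triangles for males and circles for females; dashes with bars are mean ± SD (n = 5) for the 2 families listed above 0 in each sample. Turicibacteraceae lie at 0 in the 6 samples from males, Anaeroplasmataceae are highest in cKO replicate 4 at 1.16%, and Deferribacteraceae are either at most 0.0731% or at least 0.501% in both genotypes.

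Sex was given by the titles and was balanced over genotype. Turicibacteraceae, represented by the spore-forming genus Turicibacter, were higher in females. They were listed at 0.0195% and 2.68% in the control females, at 5.25% and 0.186% in the cKO females, and at 0 in 6 of 6 samples from males. Because the males were all at 0 and depth was not estimated, no fold is given. In the limma fit with genotype as a covariate this was the 1 of 29 families that passed (adjusted p = 0.0275), and 4 families had an unadjusted p under 0.05. The others of these were Streptococcaceae (log2 fold change -1.47, female minus male, 95% interval -2.60 to -0.35), the Bacteroidales without a family name (-0.98, -1.77 to -0.20) and Dehalobacteriaceae (1.09, 0.19 to 1.99), each with a limma adjusted p of 0.165.

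The call for Turicibacteraceae was kept in some other settings and lost in several. It was kept with a pseudocount of 0.001%, as centred log ratios and without the detection filter (limma adjusted p = 0.00268, 0.0170 and 0.0456). It was also kept without control replicate 3 or 4 and without cKO replicate 3 or 5. The exact permutation test gave p = 0.00476, the smallest that 210 assignments allow. After adjustment over the 29 families this is 0.138. The exact test could therefore not pass for 1 family alone, and its adjusted p does not bear on the call. Limma's adjusted p was 0.156 with a pseudocount of 0.1% and 0.0747 with cKO replicates 1 and 2 averaged. It was 0.0581, 0.0649 and 0.102 without control replicate 1, 2 or 5, and 0.0764, 0.0675 and 0.0929 without cKO replicate 1, 2 or 4.

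The genotype difference was also compared between the sexes. The smallest p belonged to Eubacteriaceae, Ruminococcaceae and Clostridiaceae, all clostridia. Ruminococcaceae averaged 4.50% in control males and 3.57% in cKO males, against 3.27% in control females and 6.69% in cKO females, an interaction of 1.64 on the log2 scale (95% interval -0.76 to 4.03). Clostridiaceae averaged 0.505% and 0.263% in control and cKO males and 0.105% and 0.429% in control and cKO females (3.22, 95% interval -1.70 to 8.13). Single samples with unlike genera carried the cKO means of this family. The male cKO replicate 1 held 0.724%, of which 0.418% was Candidatus Arthromitus. The female cKO replicate 4 held 0.740%, of which 0.644% was the genus listed as 02d06. The other cKO samples held 0.0134% to 0.119%. Eubacteriaceae lay at or below 0.0110% in each sample (-1.11, 95% interval -2.68 to 0.47). With limma, 0 of 29 families passed, 0 had an unadjusted p under 0.05, and the adjusted p of these 3 families was 0.760. Over the alternatives the interaction ran from 1.13 to 2.35 for Ruminococcaceae, 1.94 to 4.64 for Clostridiaceae and -3.91 to -0.15 for Eubacteriaceae. Each had an unadjusted p under 0.05 in 1 of them, without cKO replicate 2, without cKO replicate 1 and with a pseudocount of 0.001%, in that order. The limma adjusted p there were 0.504, 0.770 and 0.799, and none passed. With 2 samples from females per genotype, the intervals leave room for large differences in either direction.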

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

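Each test of an explanation in this part was chosen after the result it concerns had been seen. Among 88 groups of 5 samples, the named taxa, groups and indices by genotype, 8 held a sample far from the other 4 (Dixon's test). Chance flags about 1 in 20 groups of normally distributed values. The values here hold many zeros, and 2 of the flags are related indices of the same sample, so the number of flags is not set against chance. In Turicibacteraceae the flagged sample was control replicate 5, at 2.681% against 0% to 0.0195% in the other controls. For the same family cKO replicate 4, at 5.25% against 0% to 0.186% in the other cKO samples, was not flagged on the log2 scale. In Tenericutes the flagged sample was cKO replicate 4, at 1.221% against 0.0221% to 0.300%, which carried most of the cKO mean. The same sample alone among the cKO samples held Allobaculum, at 0.1958% against 0% in the others, where any single value above 0 meets the rule. Prevotella was lowest in cKO replicate 2, at 0.7388% against 1.25% to 1.54%.

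Segmented filamentous bacteria stood out in 1 sample of each genotype, at 0.2458% in control replicate 1 against 0% to 0.00731% in the other controls, and at 0.4179% in cKO replicate 1 against 0% to 0.0314% in the other cKO samples. Control replicate 2, the sample with the f+ title, had the lowest diversity of the controls, with a Shannon index of genera of 1.502 against 1.79 to 1.90 and an inverse Simpson index of 2.243 against 3.26 to 3.48. Similar values occurred in cKO replicates 1 and 3, with Shannon indices of 1.48 and 1.51 and inverse Simpson indices of 2.10 and 2.63. No interaction of genotype and sex passed in families, and 0 of 53 measures moved in opposite directions in males and females with complete separation of the genotypes in both. At class and order level the smallest exact permutation p was 0.0556, for Mollicutes, the class of Anaeroplasma, with an adjusted p of 0.611.

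Turicibacteraceae were above 0 in 4 of 4 samples from females and 0 of 6 from males. As the source of the males' zeros, a shallower depth is argued against by 3 of the 4 females. They lay above 0.0913%, which is 10 times the highest of the smallest values above 0 in the males' family tables. Control replicate 4, at 0.0195%, did not. Whether the male libraries were shallower was not tested. Chance was not excluded: of 100 splits of the samples into groups of 6 and 4, the real one included, 7 gave at least as many families as the real 1, and the highest other gave 4. Shared housing of the females may also underlie it, and cannot be told apart from sex, because the labels name no cages and either would bring the females closer to each other (mean Bray-Curtis 0.183 between females, 0.221 to males, exact lower-tail permutation p = 0.157). An effect of sex itself stays open.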

How the results depend on the processing

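The numbers of families, genera, species-level taxa, phyla and groups that differed between genotypes, and of families with an interaction, stayed at 0 under each alternative run. For phyla, groups and the exact tests in place of limma, no taxon or group could pass alone after adjustment. Their counts of 0 therefore say little. No paired analysis was possible because the titles of the 2 genotypes share fewer than 2 numbers. Over 183 settings of the design's results, 172 kept their side of the threshold, and the other 11 concern families that differed between males and females. That count was 1; it was 0 with a pseudocount of 0.1% and 0 with cKO replicates 1 and 2 averaged, and 2 as centred log ratios, where Bacteroidales without a family name joined Turicibacteraceae. With samples left out in turn it ranged from 0 to 3: it was 0 without control replicate 1, 2 or 5 or cKO replicate 1, 2 or 4, 3 without control replicate 3 (Streptococcaceae and Dehalobacteriaceae added) and 2 without cKO replicate 3 (unresolved Clostridiales added). The cause was not tested. Where a left-out sample left 1 female in a genotype, the interaction fit assumed that it varied like the others.

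Among 53 single taxa, sums and phyla, 935 of 943 settings kept the call or its absence, the other 8 being Turicibacteraceae between the sexes. The sign of a difference that passed in neither fit changed in 96 of these settings and in 11 of the design's, for the Firmicutes to Bacteroidetes ratio, the Shannon index and the number of genera. The adjusted p of Anaeroplasmataceae was lowest without cKO replicate 5, at 0.0833. Genotype's share of the distances ran from 0.585% to 7.57% (lowest exact p 0.579). What depth limits was not worked out, since depth was not estimated. Values of 0 and the number of genera depend on it.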

Other observations

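Several families were high in the same 5 samples, which were of both genotypes. Deferribacteraceae, represented by the mucus-dwelling Mucispirillum, stood at 0.931% and 0.908% in control replicates 3 and 4 and at 0.677%, 1.03% and 0.501% in cKO replicates 2, 4 and 5, and at 0.0278% to 0.0731% in the other 5 samples. These samples held more of the sulfate-reducing Desulfovibrionaceae, at 0.725% to 0.924% against 0.102% to 0.475%, and more clostridia without a family name, at 21.2% to 25.4% against 4.88% to 15.7%. Ruminococcaceae had 3.73% to 8.42% in them and 1.35% to 3.68% in the others. Oscillospira, a genus of that family, had 2.57% to 5.14% in them and 0.725% to 2.49% in the others. Lachnospiraceae overlapped, at 2.72% to 6.83% against 1.08% to 3.15%, and so did Dehalobacteriaceae, at 0.0979% to 0.262% against 0.0474% to 0.141%. Streptococcaceae went the other way, at 0% to 0.0334% against 0.0201% to 0.0592%. These samples were picked out by their values and are not a group of the study.

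Some taxa were listed in only 1 or 2 samples. Peptostreptococcaceae stood at 0.867% in control replicate 5 and at 0 in the other 9 samples. The clostridial genus listed as 02d06 stood at 0.644% in cKO replicate 4 and at 0.0146% in control replicate 5. Desulfovibrio made up most of the Desulfovibrionaceae in control replicates 4 and 5 (0.466% and 0.131%) and cKO replicates 3 and 5 (0.0712% and 0.773%), and an unnamed genus did in the other 6 samples.

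All tests of explanations below were chosen after the results had been seen. The genotype split gave 0 families, 0 genera and 0 species-level taxa. Each of the 100 drawn splits of the samples, 100 of 100 with the real one, gives at least 0 by construction, so the splits test nothing here. The highest other split gave 7 at each level. At family level that split parted control replicates 3 and 4 and cKO replicates 2, 4 and 5 from the rest, with 6 families higher in them and Streptococcaceae lower, and Dehalobacteriaceae did not pass as centred log ratios (limma adjusted p = 0.0889). Some split must give the most, and no chance value for the highest of 100 was computed, so whether the 7 families reflect a structure of the samples stays open.

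Deferribacteraceae stood at a lower and a higher level with no sample between them. The higher level held 2 of the 5 controls and 3 of the 5 cKO samples, which were 3 of the 4 samples from females and 2 of the 6 from males. A shared factor per sample, such as a fall of S24-7 that lifts the shares of all other families, is argued against as the whole cause. The levels were 6.86-fold apart as percentages, from 0.0731% to 0.501%, and 6.18-fold apart relative to the geometric mean of the 29 families. Cage, litter and age are not in the labels and stay open, and no biological explanation was tested.

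The nearest sample by Bray-Curtis distance of families was of the other genotype for 9 of the 10 samples. If animals of both genotypes shared cages, such mixed neighbours could follow, but the exact one-sided permutation p was 0.0794 and the labels name no cages, so this cannot be told apart from chance. The nearest sample was of the same sex except for control replicate 5 and cKO replicate 4, and this was not tested. The spread between cKO samples exceeded that between controls by 0.0805 in mean distance (exact permutation p = 0.175). Sex accounted for 21.3% of the squared distances (exact PERMANOVA p = 0.148) and genotype for 1.25% (exact PERMANOVA p = 0.944). Neither share stood out among those of the other assignments. Random assignments also give shares above 0, so the 2 shares are not compared with each other.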
